A study of Paralichthys olivaceus with 12 samples.

How the data were processed

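Kidney total RNA from 12 single fish was measured on one-colour arrays, 1 array per fish. Per the labels' protocols, RNA was extracted with TRIzol, cleaned on a column against genomic DNA, and 200 ng with spike-in RNA were amplified and labelled with Cy3. The authors' deposited scanner files hold the spot intensity on a linear scale: the mean signal, the local background and a processed signal that the scanner software had corrected for background. Per the submitters' processing notes the software was Agilent Feature Extraction 9.5.3.1. The deposited value table of the series holds log2 values. They equalled the log2 processed signal minus the 75th percentile of each array, up to 1 constant per array of at most 0.00535, and were used as an alternative; their medians ran from -2.94 to -2.68 per array. Its scale and centring follow from that match, and no ratio direction applies to a one-colour array.

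The values analysed were log2 of the processed signal minus the 75th percentile of each array over the 14313 probes that are not controls. Spots with an outlier flag were set to missing, which affected 2 spots, and no probe was saturated. Probes well above background on at least 3 of the 12 arrays were tested, 12232 in all, and 1331 probes were well above background on none. The 75th percentile of the processed signal was 304.1 to 572.1 between arrays, and the spike-in calibration had a slope of 1.01 to 1.04 with a squared correlation of 0.997 to 0.998. Arrays correlated with the others of their group at a mean r of 0.930 to 0.972 across probes. Signal over background and the number of arrays set the precision. For 29 pairs of tested probes with the same sequence under different names, the log2 fold changes for virus against control differed by a median of 0.058.

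Groups came from the labels. A single linear model with the 4 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), which leaves 8 residual degrees of freedom, and p-values were adjusted by Benjamini-Hochberg over probes within each comparison, with calls at adjusted p under 0.05. The 6 comparisons were virus against control, oil against control, virus-and-oil against control, against virus and against oil, and the interaction. The fish are separate animals. The labels number them, and some numbers recur between groups. Number 5 occurs in control, virus and virus-and-oil fish, and number 8 in control and virus-and-oil fish. Numbers 6 and 7 occur in virus and oil fish, and number 2 in oil and virus-and-oil fish. No label says that a shared number links fish. The arrays lay on 3 slides, each scanned once, and each slide held 1 array of every group. The position within the slide was the same for all 3 arrays of a group, so position and group cannot be told apart by design. A probe not well above background on any array of a group has only a bound there, given as at least N-fold from the mean of the brighter group against the dimmer group, with each dim array at the higher of its own signal and its lowest signal among probes well above background.

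Before the data were examined, 24 gene lists and a rule for named genes were fixed: per comparison, the 10 called probes with the largest fold change in each direction whose groups do not overlap, plus sentinel genes and list members, with unnamed probes passed over. All 14313 probe descriptions read as unknown, 0 target names matched the RefSeq gene table of assembly ASM2471397v2, and 0 of the 24 lists had a measured member. The list tests and named genes were therefore not run. In their place, at most 2 targets per direction and comparison are given by identifier, taken by the same ranking with the brighter probe of a target; this was chosen after the annotation was seen.

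The fit was tested on simulated values of the 12232 probes with 200 changed probes. For virus against control it called 14.9% of those changed 2-fold, 56.7% of those changed 4-fold and 87.9% of those changed 16-fold, with 4 false calls. For the interaction the shares were 1.49%, 41.8% and 78.8%, with 4 false calls. The simulated noise was independent between probes and equally wide in every fish, so these values need not hold for the real arrays. The infection score gave 0.33 for a simulated fish made with 0.3 of the infection effect. Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed signal, scaling to the median of probes detected on all arrays, the deposited value table, no filter and a stricter filter on dim probes, the slide and the fish number as blocks, fits of only the groups compared, and each array left out in turn. Scaling to the 6 brightest spike-in probes, 1 probe per target, weights per array, the score that treats virus and virus-and-oil fish alike, and the infection effects under each scaling were added after the data were seen. Figures were drawn with matplotlib 3.10.9.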

Results

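Kidney gene expression was measured in 12 Japanese flounder (Paralichthys olivaceus), a marine flatfish, sampled on day 2. Infection was with viral hemorrhagic septicemia virus (VHSV), a rhabdovirus of fish, and the second treatment was exposure to heavy oil. The design crossed the 2 treatments in 4 groups of 3 fish: control fish with neither treatment, virus fish, oil fish, and virus-and-oil fish with both. Infection came before the oil exposure. Total RNA from each fish was labelled with Cy3 and hybridised to 1 array, and fish are named by group and the number in their label. Each array carried 14313 probes of 60 bases for 12268 target names. All target names are clone, expressed sequence tag (EST) or contig identifiers, and the files do not pair them with gene names, so a few targets per comparison are given by identifier and the rest as counts. Between 10850 and 11918 probes, or 75.8% to 83.3%, were well above background on an array, and 12232 probes (85.5%) entered the tests. Levels are log2 signals relative to the 75th percentile of the array, given as mean ± SD of 3 fish. With 3 fish per group, the number of arrays limits the precision.

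Infection alone, compared between virus and control fish, changed 1348 of 12232 probes, with 751 higher and 597 lower. These probes stood for 1263 targets. Many of the called changes were large: 598 of the higher and 478 of the lower probes moved by 2-fold or more, and 65 rose and 27 fell by 16-fold or more. In simulated values the fit called 14.9% of 2-fold changes, so called probes lean towards large changes. The EST C23061 stood at 5.76 ± 0.17 in virus fish and -3.04 ± 0.13 in control fish (n = 3 each), a log2 fold change of 8.80 (SE 1.13, limma adjusted p = 0.0123). Its probe has the sequence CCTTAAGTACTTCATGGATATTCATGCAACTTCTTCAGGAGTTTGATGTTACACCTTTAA. The contig jf_gb_contig246 stood at 8.37 ± 0.15 against 0.05 ± 0.26, a log2 fold change of 8.32 (SE 1.06, adjusted p = 0.0123), with the probe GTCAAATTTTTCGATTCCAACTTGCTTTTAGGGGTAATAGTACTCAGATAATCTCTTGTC. In the other direction, CX284888 stood at -3.35 ± 1.71 in virus fish and 1.83 ± 0.11 in control fish, a log2 fold change of -5.18 (SE 1.13, adjusted p = 0.0250). After normexp background correction and quantile normalization the log2 fold changes were 7.86 for C23061, 8.12 for jf_gb_contig246 and -3.82 for CX284888. The clone PAO-8-1a-T3_M13 had a log2 fold change of -5.98 (SE 1.39, adjusted p = 0.0285), with the probe well above background in only 1 of the 3 virus fish; after normexp background correction and quantile normalization this was -2.32 (adjusted p = 0.00975), and with the slide as a block it was not called (adjusted p = 0.0540). Within the 3 slides, the virus-minus-control differences were 8.81, 8.58 and 9.02 for C23061 and -3.26, -5.45 and -6.84 for CX284888.

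The number of called probes depended on single fish. It was 6 without control fish 4, 21 without control fish 5, 138 without control fish 8, 72 without virus fish 6, 10 without virus fish 7, and 2380 (1141 higher, 1239 lower) without virus-and-oil fish 8, which enters this comparison through the shared estimate of the spread. Of the 12 fits with 1 fish left out, 2 did not call C23061 or jf_gb_contig246 and 5 did not call CX284888 or PAO-8-1a-T3_M13, though the log2 fold changes closest to 0 among the 12 were 8.70, 8.17, -4.38 and -5.11. With the slide as a block the count was 700 (407 higher, 293 lower), and with arrays scaled to spike-in RNA it was 532 (444 higher, 88 lower). The number with an unadjusted p under 0.05 was 3761 with all fish, against 611.6 expected with no effect. It was 3055, 2911 and 3198 without control fish 4, 5 and 8, and 3104 and 3040 without virus fish 6 and 7. With spike-in scaling it was 2592.

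**Figure D1:**
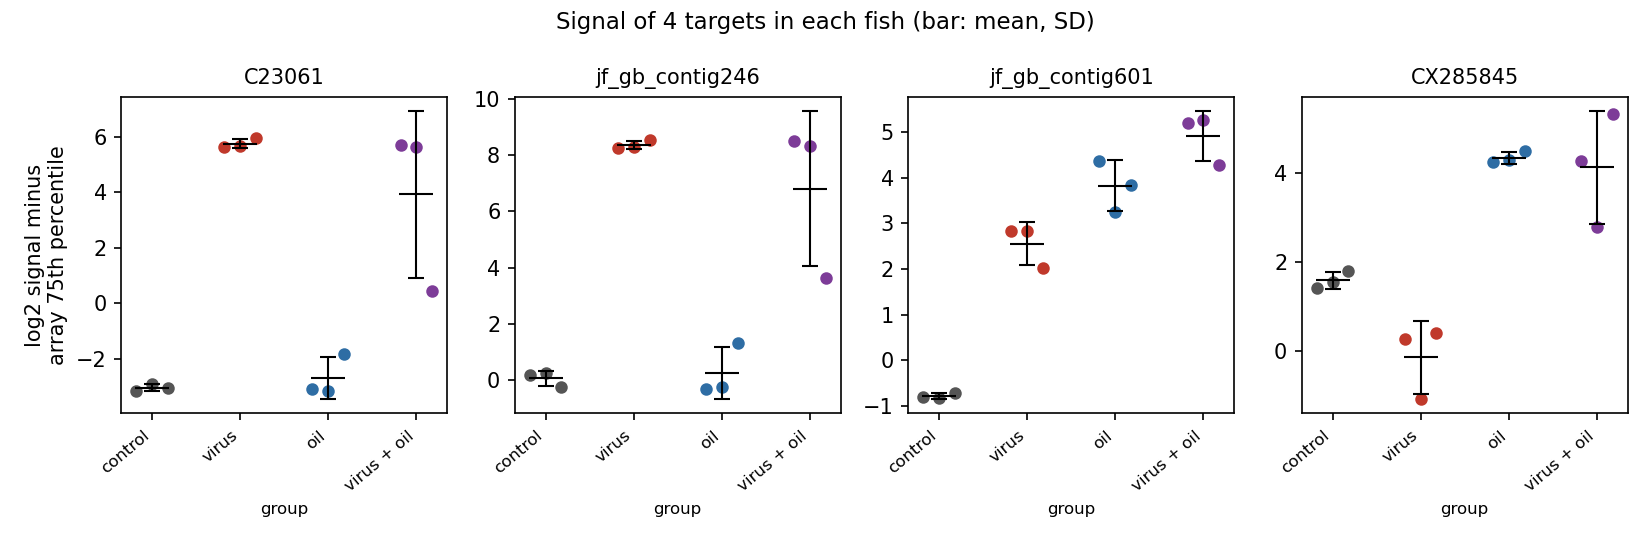
Signal of 4 targets in each of the 12 fish, on the y axis as log2 signal minus the 75th percentile of the array, by group on the x axis; points are fish, and bars are the mean and SD of 3 fish. C23061 lay at 5.76 in virus fish and at -3.04 in control fish, while 1 of the 3 virus-and-oil fish lay at 0.45; CX285845 was at 4.34 in oil fish and at 1.59 in control fish.

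Oil alone, compared between oil and control fish, changed 5 probes, 4 higher and 1 lower, while 1381 probes had an unadjusted p under 0.05 against 611.6 expected with no effect. The contig jf_gb_contig601 stood at 3.82 ± 0.56 in oil fish and -0.78 ± 0.06 in control fish (n = 3 each), a log2 fold change of 4.60 (SE 0.36, limma adjusted p = 0.00134). Its probe reads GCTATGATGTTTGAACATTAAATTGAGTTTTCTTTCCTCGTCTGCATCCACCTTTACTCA. A second probe of this target had a log2 fold change of -0.44. The EST AU091074 stood at -1.15 ± 0.11 against -3.99 ± 0.22, a log2 fold change of 2.84 (SE 0.25, adjusted p = 0.00249), and its second probe gave 1.13 (adjusted p = 0.141); after normexp background correction and quantile normalization the first gave 1.64. The oil-minus-control differences within the 3 slides were 5.18, 4.08 and 4.54 for jf_gb_contig601 and 2.97, 2.69 and 2.87 for AU091074. Of the 4 probes that rose with oil alone, 3 were also called higher in virus-and-oil than in virus fish, against 0.00294 for independent lists. Both lists use the same estimate of the spread of each probe, so they are not independent.

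The count for oil alone was 2 with the slide as a block, 47 (16 higher, 31 lower) after normexp background correction and quantile normalization, and 10 without virus-and-oil fish 8. It was 2 without control fish 4, control fish 5, control fish 8, oil fish 6 or virus fish 5, and 3 without oil fish 7. The number of probes with an unadjusted p under 0.05 was not stable either: 642 with spike-in scaling, close to the number expected, 890 without control fish 5 and 2214 with array weights.

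Both treatments together, compared between virus-and-oil and control fish, changed 1061 probes, 566 higher and 495 lower, for 1018 targets. The EST AU260980 stood at 6.15 ± 3.65 in virus-and-oil fish and -1.45 ± 0.48 in control fish (n = 3 each), a log2 fold change of 7.61 (SE 1.34, limma adjusted p = 0.0209). C23061 had a log2 fold change of 6.96 (SE 1.13, adjusted p = 0.0158), and of 5.95 after normexp background correction and quantile normalization. CL836Contig1 stood at 0.23 ± 3.57 against 5.65 ± 0.47, a log2 fold change of -5.42 (SE 1.43, adjusted p = 0.0465). CL1922Contig1 had a log2 fold change of -5.11 (SE 1.31, adjusted p = 0.0439), with the probe well above background in 2 of the 3 virus-and-oil fish. With the slide as a block CL836Contig1 and CL1922Contig1 were not called (adjusted p = 0.0645 and 0.0651), nor were they without a filter on dim probes (0.0549 and 0.0526) or with spike-in scaling (0.0822 and 0.0731), and CL1922Contig1 gave -3.23 after normexp background correction and quantile normalization. The wide SDs of this group came from fish 8: within the 3 slides AU260980 differed by 9.68, 10.29 and 2.86, and CL836Contig1 by -7.65, -6.73 and -1.88, with fish 8 on the third slide. Of the 751 probes higher in virus fish, 380 were also called higher here and 0 were called lower; of the 597 lower in virus fish, 218 were called lower here and 0 higher. Independent lists would share 34.8 and 24.2 probes. Both comparisons use the same 3 control fish, too few to split, so part of the excess may come from the shared controls. Across probes, which are not independent replicates, the fold changes correlated with r = 0.824 and a covariance of 0.854, where simulated unchanged groups against shared controls gave r = 0.496 and a covariance of 0.130.

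This count was 3116 (1383 higher, 1733 lower) without virus-and-oil fish 8, 10 without control fish 4, 33 without control fish 5, 113 without control fish 8, 25 without virus-and-oil fish 2, 40 without virus-and-oil fish 5, 484 without virus fish 7, 623 without oil fish 7, 694 without oil fish 2 and 703 without virus fish 6. It was 104 (78 higher, 26 lower) with the slide as a block, 12 in a fit of the 6 arrays of these groups, and 58 (40 higher, 18 lower) with spike-in scaling. Of the 12 fits with 1 fish left out, 5 did not call AU260980 or C23061 and 11 did not call CL836Contig1 or CL1922Contig1.

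The addition of oil in infected fish was compared between virus-and-oil and virus fish. The series title speaks of a suppression of antiviral activity by heavy oil. Without gene names, antiviral genes cannot be picked out, so the counts speak neither for nor against that. Adding oil changed 9 probes of 8 targets, all 9 higher with oil and 0 lower, and 1003 probes had an unadjusted p under 0.05. In simulated values the fit called 22.4% of 2-fold changes in this comparison, so lower probes can have been missed. CX285845 stood at 4.12 ± 1.27 in virus-and-oil fish and -0.14 ± 0.82 in virus fish (n = 3 each), a log2 fold change of 4.26 (SE 0.57, limma adjusted p = 0.0400), with differences between 3.87 and 4.90 within the 3 slides. The second probe of this target gave 2.03 and was not called (adjusted p = 0.171). The first probe is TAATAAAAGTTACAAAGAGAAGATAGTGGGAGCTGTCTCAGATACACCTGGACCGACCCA. CL1462Contig1 was not well above background in any virus fish. On the processed signal it was at least 11.2-fold higher in virus-and-oil fish (limma adjusted p = 0.0400). That bound does not carry over to another background correction. After normexp background correction and quantile normalization its log2 fold change was 1.17 and it was not called (adjusted p = 0.316). Neither target was called with the slide as a block (adjusted p = 0.109 for both) or with spike-in scaling (0.369 for both). Counted separately for each target, 10 of the 12 fits with 1 fish left out did not call it. CL1462Contig1 was well above background in all 3 oil fish, at -1.84 ± 0.38, and in all 3 control fish, at -4.30 ± 0.31. The most strongly induced targets of infection were not called here: C23061 had a log2 fold change of -1.84 (SE 1.13, adjusted p = 0.700) and jf_gb_contig246 one of -1.55 (SE 1.06, adjusted p = 0.722), and for both the differences within slides were near 0 on the first and second slides (0.06 and -0.06, and 0.24 and 0.01) and large on the slide with fish 8 (-5.50 and -4.91). The count was 0 with the slide as a block, 0 in a fit of these 6 arrays and 0 with spike-in scaling. It was 20 (13 higher, 7 lower) without virus-and-oil fish 8, 0 without any one of the 3 control fish, oil fish 2 or oil fish 6, 1 without oil fish 7, 2 without virus-and-oil fish 2 or 5, 5 without virus fish 6 and 3 without virus fish 7.

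Infection in oil-exposed fish, compared between virus-and-oil and oil fish, gave 0 called probes with limma, while 2618 probes had an unadjusted p under 0.05 and the smallest adjusted p was 0.101. C23061 had a log2 fold change of 6.61 (SE 1.13, adjusted p = 0.101) and jf_gb_contig246 one of 6.58 (SE 1.06, adjusted p = 0.101). Their differences within the 3 slides were 8.80, 8.78 and 2.27, and 8.82, 8.58 and 2.33. The number with an unadjusted p under 0.05 was 1637 without virus-and-oil fish 2, 1296 without fish 5 and 3932 without fish 8. Without virus-and-oil fish 8 the count of called probes was 2311, with 1094 higher and 1217 lower. In that fit, 758 probes were called higher in both virus against control and virus-and-oil against oil fish, where 102.0 were expected of independent lists. Lower in both were 651, where 123.3 were expected. These comparisons share no fish, but they share the estimate of the spread of each probe, which can raise the overlap. Fish 8 was singled out for its low infection response. Leaving it out favours more infection calls and more overlap, so these counts do not measure the infection effect in oil-exposed fish without bias. The count was 2 with spike-in scaling and 0 with the slide as a block.

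**Figure D2:**
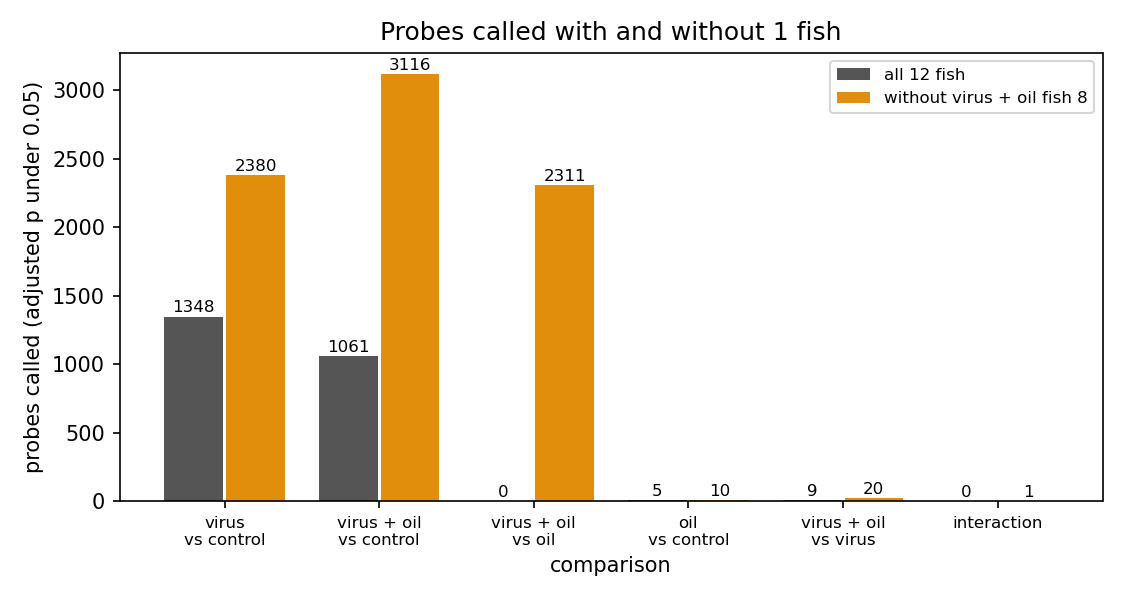
Number of probes called at adjusted p under 0.05, on the y axis, in each of the 6 comparisons on the x axis, from the fit of all 12 fish and from the fit without virus-and-oil fish 8. Infection in oil-exposed fish gave 0 called probes with all fish and 2311 without that fish. It was singled out for its low infection response, which favours more infection calls without it.

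A score placed each fish between the control mean at 0 and the virus mean at 1, over the 500 probes of smallest p in virus against control fish, with each control or virus fish scored on probes and means found without it. Control fish scored 0.042 ± 0.021 and virus fish 0.872 ± 0.128 (n = 3 each). Oil fish scored 0.103 ± 0.037. Among the virus-and-oil fish, fish 2 scored 1.07, fish 5 scored 1.06 and fish 8 scored 0.247. The group mean was 0.792 ± 0.473, and since virus fish were left out of their own score and virus-and-oil fish were never in it, the groups were also scored alike, with 1 virus fish left out of the score in turn. The means were then 0.759 ± 0.451 in virus-and-oil and 0.872 ± 0.128 in virus fish, a difference of -0.113 (exact permutation test that rebuilds the score for each relabelling of the 6 fish, two-sided, p = 0.950, where the smallest p is 0.05).

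**Figure D3:**
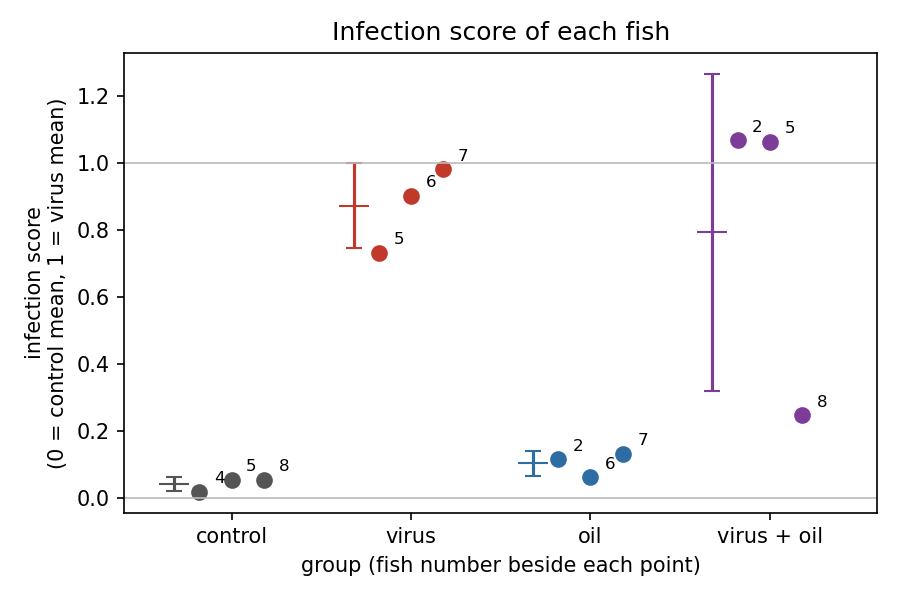
Infection score of each of the 12 fish on the y axis, by group on the x axis, with the fish number beside each point and the mean and SD of 3 fish to the left. Virus-and-oil fish 2 and 5 scored 1.07 and 1.06, and fish 8 scored 0.247, above the oil fish at 0.062 to 0.132.

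Whether oil altered the infection effect was tested as the interaction of both treatments. Limma called 0 probes, 731 had an unadjusted p under 0.05 (468 without oil fish 6 and 1148 without oil fish 7), and the smallest adjusted p was 0.651. The interaction was -2.19 (SE 1.59, adjusted p = 0.807) for C23061 and -2.25 (SE 0.51, adjusted p = 0.787) for jf_gb_contig601, which was higher than in control fish by 3.34 on the log2 scale in virus fish, by 4.60 in oil fish and by 5.69 in virus-and-oil fish. The second probe of jf_gb_contig601 gave 0.02 in virus, -0.44 in oil and -0.25 in virus-and-oil fish. Without virus-and-oil fish 8, 1 probe was called, CL1922Contig1, with an interaction of -3.87 (adjusted p = 0.00881); the probe was well above background in only 1 of the 2 virus-and-oil fish left, so the size rests on a dim signal. Across the 12232 probes, which are not independent replicates, the infection effect in oil-exposed fish correlated with that in unexposed fish with Pearson r = 0.725 and Spearman rho = 0.631. Among the 1423 probes called higher for the mean of both infection effects, the median log2 fold change was 1.12 without oil and 0.89 with oil, and among the 1361 called lower it was -1.25 and -0.97. The effect was the smaller one with oil at 73.0% and 68.6% of these probes. For the lower probes the share was 67.6% after normexp background correction and quantile normalization. It was 65.8% after quantile normalization and 68.9% after median scaling, but it changed with spike-in scaling. Spike-in scaling also moved the median interaction of all tested probes from 0.06 to -0.58, and its shares include that shift. With spike-in scaling the medians were 2.04 without and 1.11 with oil over 608 higher probes, and -1.62 and -1.80 over 584 lower probes, and the effect was the smaller one with oil at 95.2% and 43.2% of them. In single virus-and-oil fish, the median of the higher probes relative to the oil mean was 1.08 in fish 2, 1.24 in fish 5 and 0.36 in fish 8. Without fish 8 the medians were 1.003 without and 1.11 with oil over 1837 higher probes, -0.99 and -1.22 over 2225 lower probes, and the effect was the smaller one with oil at 43.8% and 38.8% of them. With 2 virus-and-oil fish left, the groups are unequal, and choosing probes by the mean of both effects favours larger effects with oil. Fish 8 was also left out because of its low infection response, so these shares cannot show a larger effect with oil.

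**Figure D4:**
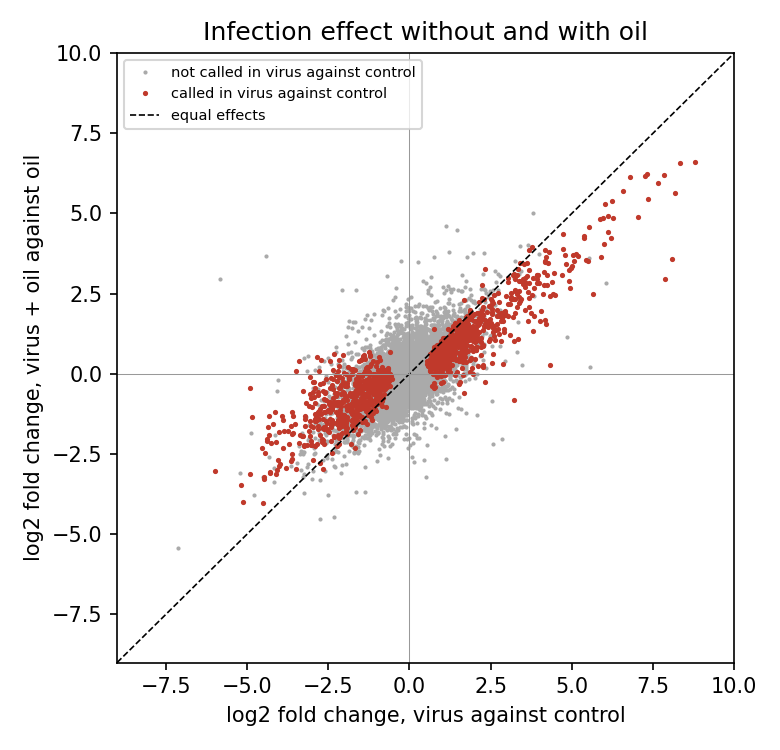
Log2 fold change of each of 12232 probes for virus-and-oil against oil fish on the y axis and for virus against control fish on the x axis, with the probes called in the latter in red and a dashed line of equal effects. The correlation across probes was 0.725.

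The oil effect in infected fish correlated less closely with that in uninfected fish, with Pearson r = 0.265 and Spearman rho = 0.194 across the 12232 probes. Oil had 9 and 5 called probes against 1348 for virus against control, so noise weighs more on this correlation. The low infection response of fish 8 also enters the oil effect in infected fish. The lower value therefore does not show that the oil response depended more on the other treatment. Among the called targets, jf_gb_contig601 had a log2 fold change of 4.60 without infection and 2.35 with it (adjusted p = 0.0557), AU091074 one of 2.84 and 1.83 (adjusted p = 0.0407), and CX285845 one of 2.75 (adjusted p = 0.171) and 4.26. Second probes gave -0.44 and -0.27 for jf_gb_contig601, 1.13 and 1.41 for AU091074, and 1.45 and 2.03 for CX285845.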

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

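The tests of the infection calls in this part were chosen after the result was seen. A signal in data outside the comparisons differed between groups: the scanner software's ratio of negative-control to background signal was 0.971 ± 0.048 in control, 1.06 ± 0.04 in virus, 1.20 ± 0.07 in oil and 1.37 ± 0.03 in virus-and-oil arrays (SD, n = 3 each), a difference of 0.400 between the last and the first. It rose with array position from 1 to 4 on all 3 slides, which is how it was noticed, and position follows group on every slide. A gradient along the slide as the source of the infection calls is argued against by the infection score, since oil fish at position 3 would then lie above virus fish at position 2, while the lowest virus fish lay 0.599 above the highest oil fish. For the oil calls, the averaged infection effect steps 1 position where oil steps 2. A gradient in equal steps needs it to run the same way as the averaged oil effect. It did so at 22 of the 44 probes called for the averaged oil effect, or 50%. That speaks against equal steps as their whole source, unless infection itself turned the sign. Of the 44, 12 were called for averaged infection the same way and 6 the opposite way. A gradient that rises mainly between positions 2 and 3 would look like an oil effect and stays open. So does an effect of position on single probes that does not follow the order of positions, and no biological explanation of the ratio was tested.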

How the results depend on the processing

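Spike-in scaling, array weights and 1 probe per target were chosen after the data were seen. The counts for virus against control, virus-and-oil against control and virus-and-oil against virus stayed within 1.5 times under normexp with quantile, quantile, median scaling, the deposited table, the stricter filter and 1 probe per target. Normexp with quantile called 47 probes for oil and gave 0.806 for the correlation of infection effects. Without a filter on dim probes, virus-and-oil against control gave 671 probes and the interaction 1. The slide block gave 700 for virus, 2 for oil, 104 for virus-and-oil against control and 0 for virus-and-oil against virus. Only the arrays of both groups gave 12 for virus-and-oil against control and 0 against virus. Spike-in scaling gave 532 for virus, 58 for virus-and-oil against control, 0 against virus and 2 against oil, and moved the median of all probes to 0.16, -0.25, -0.40 and -0.38, and to 0.17 for oil and -0.58 for the interaction. Array weights, lowest for virus-and-oil fish 8, gave 3530 for virus (1955 lower), 51 for oil, and 4285 (2489 lower), 19 and 1829 for virus-and-oil against control, virus and oil, so that most calls against control in infected fish were lower. Causes of these changes were not tested.

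With the fish number as a replicate block, limma called 0 probes for virus, oil, and virus-and-oil against control and against virus, and 784, 409, 1443 and 416 had an unadjusted p under 0.05; the block uses up most degrees of freedom. Fish with the same number did not deviate together on average (mean r of 0.0038 over 7 pairs, from -0.263 to 0.256). Fish with other numbers ranged from -0.290 to 0.361. The pairs are too few and too spread to exclude a link between fish of the same number.

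Leaving out 1 fish in turn gave 6 to 2380 probes for virus, 2 to 10 for oil, 10 to 3116, 0 to 20 and 0 to 2311 for virus-and-oil against control, virus and oil, 0 to 1 for the interaction, and correlations of 0.603 to 0.765 for infection and 0.155 to 0.335 for oil effects. Of 280 values of the 11 named targets under alternatives, 187 kept direction and call, 92 kept the direction but not the call, and 1 reversed, the second probe of jf_gb_contig601 in oil against control at -0.44. The gene list tests and named genes were not run, for want of gene names. Probe GC content correlated with fold change at 0.081 or less in size. Dim probes limit fold changes of low targets.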

Other observations

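The tests of fish 8 and of the probe pairs in this part were chosen or revised after the result was seen. Averaged over infection, an oil effect was called by limma at 44 probes of 41 targets, 22 higher and 22 lower; this contrast was looked at after the data were seen. Among them CX285845 rose by 3.50 on the log2 scale (SE 0.40, adjusted p = 0.00757) and jf_gb_contig601 by 3.48 (SE 0.25, adjusted p = 0.000587). The clone PAO-1-4a-T3_A12 had an oil effect of -1.56 (SE 0.22, adjusted p = 0.0206). Some of these probes were also called for infection averaged over oil, 12 in the same direction and 6 in the opposite one: jf_gb_contig601 rose by 2.21 (adjusted p = 0.00277), and PAO-1-4a-T3_A12 fell by 1.27 (adjusted p = 0.00682), while CX285878, with an oil effect of -1.12 (adjusted p = 0.0382), rose with infection by 0.87 (adjusted p = 0.0112). CX285845 had an infection effect of -0.97 (adjusted p = 0.104). The second probe of jf_gb_contig601 did not rise with oil, at -0.44 against control and -0.27 against virus fish. For infection it gave 0.02 without oil and 0.20 with it. These 4 targets were chosen after their values were seen.

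Virus-and-oil fish 8 scored 0.247 for infection where its group mates scored 1.07 and 1.06. Its array correlated best with that of oil fish 7 (r = 0.980 across probes), which lay next to it on the same slide. The array of control fish 5 also correlated best with an oil fish (r = 0.975). A mislabelled fish kept without oil is argued against: at all 6 probes called for oil in a fit of oil and control fish, or 100%, fish 8 lay beyond all 6 fish without oil. Chance gives 14.3% where the fish play no part in the choice of probes. The control fish did play a part, so the share by chance can be higher, and the 6 probes may not be independent. An oil-exposed fish that was never infected is left open, since fish 8 lay above all 3 oil fish at 42.0% of the 993 probes induced by infection and at 26.8% of all probes, between the bounds set for it. The test was first written for the 100 most induced of these with a higher bound, and there the share was 56%, also between bounds. The induced and the lowered probes differ: at the 66 probes induced over 16-fold fish 8 lay above all oil fish in 60.6%. At the 206 induced 4- to 16-fold it did so in 36.4%, and at the 521 induced 2- to 4-fold in 39.7%. At probes lowered 2- to 4-fold, 4- to 16-fold and over 16-fold it lay below all of them in 24.5%, 22.3% and 20.7%, near the share of chance. Carry-over of infected RNA into such a fish is left open too: at probes induced over 16-fold, fish 8 reached 2.36% of the linear rise of its group mates (oil fish -0.71% to 0.65%), and at those induced 2- to 4-fold 9.76% (oil fish -6.22% to 3.01%), a ratio of 4.14 whose difference is within the range of the oil fish. At those induced 4- to 16-fold it reached 2.60% (oil fish -2.63% to 1.34%), close to the 2.36%. A slower or weaker infection of that fish, with or without a part played by oil, was not tested and may account for it.

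Of the targets, 2045 had 2 probes, and where their sequences overlapped they lay on opposite strands (107 pairs, against 0 on the same strand); for the other pairs the strands are not known. In virus against control the 2 probes mostly moved the same way. Of 220 pairs whose brighter probe was called there, the dimmer moved the same way in 87.3% and was called the same way in 38.2%. The median ratio of log2 fold changes was 0.728. Over the 1434 pairs with both probes tested, log2 fold changes correlated at 0.720 for virus against control. For oil against control the correlation was 0.394, and for the interaction 0.367. Only 11 of the 220 were overlapping pairs, and of these 9 moved the same way. If the probes lie on opposite strands, a candidate explanation is labelled product of the opposite strand in proportion to the target, which needs the brightness of both probes to rise together. Over 519 pairs more than 16-fold apart it did, at r = 0.606, but partners shuffled at random and chosen by the same gap gave 0.311, so the choice of pairs fixes part of that value. The test is therefore void, and the cause is left open.

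For each comparison of 3 against 3 fish there are 10 splits, too few for a share under 0.05. Of the 10, 1 split, the real one, called as many probes for virus against control (1348, highest other 0), oil against control (5, highest other 0), virus-and-oil against control (1061, highest other 2) and virus-and-oil against virus (9, highest other 5). For virus-and-oil against oil (10 of 10 splits, highest other 18) and the interaction (100 of 100 drawn splits, highest other 2893) the real count is 0, which every split reaches, so these values say nothing about chance. The 2 interaction splits with the most calls, 2893 and 2549, had 6 and 1 of the 6 infected fish in the 2 groups that the interaction adds, where the real grouping has 3. Another 6 splits with 1 or 5 infected fish there called 0, so many calls point to a structure of the samples that the number of infected fish alone does not give.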
